A study of Homo sapiens with 9 samples.

How the data were processed

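Total RNA was measured in SMS-KCNR, an established human neuroblastoma cell line, on 9 one-channel Affymetrix whole-transcript arrays with biotin-labelled target, per the labels' protocols. The labels give 3 groups of 3 arrays, all collected after 30 hours. One group received the solvent DMSO, another 5 µM simvastatin, and the remaining group the same dose of the drug together with mevalonate (2 mM). The series' design text calls the samples of each group independent. It does not say whether they were separate cultures grown on separate days, so the p-values cover the spread between these samples, which can be partly technical.

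The deposited values are on the log2 scale, 1 value per probeset and array, as made by the authors. Their scale was read from the values, which ran from about 1 to 14 on each array with medians from 5.17 to 5.21 and nearly equal quartiles. The submitters' processing notes name GCRMA and HOMER without versions or roles. GCRMA corrects background with probe sequence, normalizes between arrays and summarises probes into probesets, but which of these steps was run, and with which settings, is not given in the sources used here. The genome build behind the probe annotation is not given either, so no coordinates are printed. GCRMA-type background correction and normalization between arrays place dim probesets close together and force the arrays to share 1 overall distribution. Changes of dim genes are therefore poorly determined, and a change of all genes in 1 direction would not be visible. No detection calls were used here, and the number of arrays limits the precision.

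Of the 53617 probesets, 16098 (30.0%) carried 1 gene symbol in the platform annotation used here, 0 carried several and 37519 had no symbol. All 16098 named probesets matched a gene of the RefSeq table (assembly GCF_000001405.40, GRCh38.p14) through their Entrez identifier, and 0 symbols changed. Where a gene had several probesets (779 genes), the probeset with the highest mean over all arrays was taken, which left 14884 genes. Of these, 11916 were protein-coding, out of 20056 protein-coding genes in the RefSeq table, 1398 were long non-coding RNA genes and 1072 were microRNA genes. A microRNA symbol on these arrays stands for a probeset at the gene, not for a mature arm. MYCN and CDKN1A are not analysed here.

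Differences between groups were estimated in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, without trend and not robust). The 9 arrays entered 1 fit with 3 group means and shared 1 estimate of each gene's spread (6 residual degrees of freedom, prior degrees of freedom 2.39). The median within-group SD was 0.0927 on the log2 scale. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over the 14884 genes, with a threshold of 0.05. Errors of log2 changes are limma's standard errors. A fold is 2 to the power of the log2 change of the deposited values. "Rose", "fell" and "changed" are used of genes past that threshold. The simvastatin arrays enter both the comparison with DMSO and the comparison with simvastatin plus mevalonate, so these comparisons share chance values. That share was measured with 50 simulated sets of arrays that had the measured spread and no differences, and with sets in which mevalonate had no effect or returned every gene in full.

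Before the data were examined, 29 gene lists (606 entries) were written down for pathways a statin or mevalonate can be thought to touch, for neuroblastoma cell identity and for markers of other cell types or states. Of the entries, 382 were measured (373 genes), from 3 to 29 per list. Lists were tested with limma's camera, which asks whether a list shifted relative to the other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 29 lists. As alternatives, camera was run with the correlation estimated from the data, and fry was run, which asks whether the members move, on balance, 1 way. Counts "adjusted over the list alone" repeat the Benjamini-Hochberg step within the list. The genes named in the report follow a rule set in advance. For each comparison these are the 10 largest rises and the 10 largest falls among changed genes whose groups do not overlap, leaving out symbols that start with LOC, LINC, MIR, SNOR, SCARNA, RNU, RNA5 or OTTHUM. Added to them are up to 4 members per list with the largest absolute change, and HMGCS1, RHOB, KLF2, MYCN and CDKN1A in every comparison. Of the 29 lists, 1 and some genes of the rule are not reported here, though that list is included in the counts of lists and in the adjustment.

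The procedure was tested on simulated data with the spread of these arrays for simvastatin against DMSO, with 14884 genes and 200 changed genes in each of 10 sets. It called 70.7% of genes changed by 0.5 on the log2 scale, 94.5% of those changed by 1 and 99.2% of those changed by 2. Among unchanged genes, 106 of 146840 (0.0722%) were called. A shift of 0.5 in the cholesterol synthesis list was called in 10 of 10 sets, and 0 of 280 tests of the other lists were called. The simulated genes varied independently of each other. The list result therefore does not show how often lists are called falsely where genes vary together.

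Alternatives fixed before the data were examined were a trended and robust eBayes, a fit of only the arrays compared, the replicate number as a block, the removal of dim genes, the mean over a gene's probesets, quantile normalization, median centring, an offset of 16 on the linear scale, array quality weights, leaving out each array, a threshold of 0.01, 2 other definitions of a gene moved back, and the other list tests. A count over all probesets and a fit of protein-coding genes only were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.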

Results

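Gene expression was measured in SMS-KCNR neuroblastoma cells, a line of tumour cells of the sympathetic nervous lineage, after 30 hours with DMSO, simvastatin (5 µM) or simvastatin plus mevalonate (2 mM), with 3 arrays per group. Simvastatin is a statin, a drug that blocks the synthesis of mevalonate. Mevalonate is the precursor of cholesterol, of the isoprenoids attached to prenylated proteins, and of ubiquinone and dolichol. Each array gave a log2 value for 53617 probesets, of which 14884 genes with a name were compared. Arrays of the same group correlated across these 14884 genes with r from 0.994 to 0.996. DMSO arrays correlated with simvastatin arrays at 0.990 to 0.992 and with simvastatin plus mevalonate arrays at 0.994 to 0.996.

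To determine what simvastatin changed against its solvent, the simvastatin and DMSO arrays were compared first. Genes of cholesterol and fatty acid synthesis and of the amino acid stress response rose, and genes of mitosis fell. In total 1988 of 14884 genes changed (limma, adjusted p under 0.05), 890 upward and 1098 downward, with a median absolute log2 change of 0.34. Of these, 41 changed at least 2-fold, 18 upward and 23 downward. With quantile normalization the balance turned, with 1048 upward and 1001 downward. Of the 1988 changed genes, 1985 had groups that did not overlap. Over all genes 28.6% had groups that did not overlap, where chance gives 10%.

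The largest rise was that of DHCR7, which catalyses the last step of cholesterol synthesis. Its log2 value went from 7.27 ± 0.14 (SD, n = 3) with DMSO to 9.30 ± 0.10 with simvastatin, a 4.07-fold rise (adjusted p = 4.77e-06). HMGCS1, an early enzyme of the pathway, rose 3.17-fold (log2 change 1.66 ± 0.05 SE, adjusted p = 3.08e-06). Among the 14 measured members of the cholesterol synthesis list, 10 rose and 0 fell (11 rose when adjusted over the list alone), including ACAT2 (1.40 ± 0.05) and MVD (0.89 ± 0.05). The list shifted upward with a mean log2 change of 0.67 (camera, adjusted p = 6.17e-12). Of 14 measured genes of fatty acid synthesis, 11 rose (13 adjusted over the list alone), with ACSS2, which makes acetyl-CoA from acetate, at 1.42 ± 0.11, FASN, the fatty acid synthase, at 0.84 ± 0.05, and the desaturases FADS1 and SCD both at 0.49 (adjusted p for the list = 3.85e-11). In the sterol uptake and sensing list 4 of 7 members rose (5 rose and 1 fell adjusted over the list alone). They were the transcription factor gene SREBF2 (0.65 ± 0.06), INSIG1 (0.55 ± 0.06) and INSIG2 (0.30 ± 0.06), which retain SREBP proteins in the endoplasmic reticulum, and STARD4 (0.35 ± 0.06), a sterol carrier. This list had an adjusted p of 0.00225, and an adjusted p = 0.107 with an estimated correlation.

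**Figure D1:**
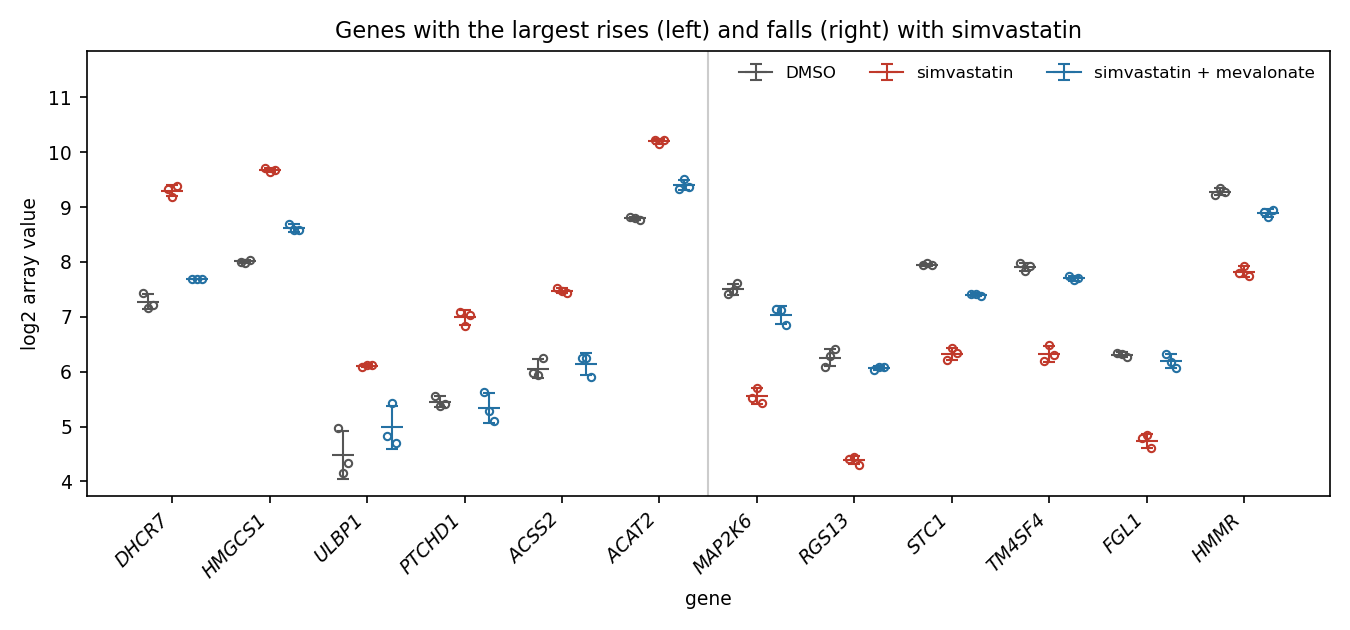
Log2 array values (vertical axis) of the 6 genes with the largest rises and the 6 with the largest falls with simvastatin (horizontal axis), in 3 groups. Circles are single arrays (n = 3), horizontal marks are means and bars are SDs; DHCR7 stands at 7.27 with DMSO and 9.30 with simvastatin, and with mevalonate each gene lies nearer to DMSO than with simvastatin alone.

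Genes controlled by ATF4, a transcription factor of the response to amino acid shortage and other stresses, rose as a group. Of 18 measured members 14 rose and 0 fell (15 rose adjusted over the list alone), and the list's mean log2 change was 0.61 (adjusted p = 2.21e-16). SESN2 (1.20 ± 0.14), an inhibitor of the growth kinase mTORC1, ASNS (1.19 ± 0.06), the asparagine synthetase, DDIT4 (1.12 ± 0.07), another inhibitor of mTORC1, and TRIB3 (1.11 ± 0.12), a pseudokinase, led the list. In the serine, glycine and one-carbon list 5 of 9 members rose and 2 fell (5 and 2 adjusted over the list alone). MTHFD1L (0.66 ± 0.04), PSAT1 (0.65 ± 0.04) and SHMT2 (0.41 ± 0.04) were among those that rose (adjusted p for the list = 0.0229, and adjusted p = 0.104 with an estimated correlation). Without DMSO replicate 1 or 3 or any simvastatin array, 1 member fell in place of 2, and without simvastatin replicate 3 only 3 rose. Of 11 endoplasmic reticulum chaperone and quality-control genes 4 rose (4 adjusted over the list alone), led by XBP1 (0.85 ± 0.06), a transcription factor of the unfolded protein response. HYOU1 (0.36 ± 0.04) rose by its brightest probeset, a call lost with the mean over its probesets (adjusted p = 0.0668). The list had an adjusted p of 0.00453, and an adjusted p = 0.0647 with an estimated correlation. In the ribosome biogenesis list 3 of 15 members rose (6 adjusted over the list alone), with RRP12 at 0.73 ± 0.07 and ODC1, which begins polyamine synthesis, at 0.22 ± 0.04 (adjusted p = 0.0111, and adjusted p = 0.0859 with an estimated correlation).

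Targets of serum response factor and its actin-regulated partners MRTF also rose, 7 of 13 with 0 falling (9 rose adjusted over the list alone). They included ZYX (1.09 ± 0.08) and VCL (0.61 ± 0.06), which encode the focal adhesion proteins zyxin and vinculin, and SRF itself (0.55 ± 0.04), and the list's adjusted p was 1.73e-07. In the list of immediate early and KLF genes 11 of 20 rose and 1 fell (11 and 2 adjusted over the list alone), with DUSP5 (0.90 ± 0.07), a phosphatase of the ERK kinases, IER3 (0.79 ± 0.07) and JUN (0.66 ± 0.08) leading (adjusted p = 1.27e-05, and adjusted p = 0.0647 with an estimated correlation). The call of the member that fell was lost without any single array but simvastatin replicate 1. KLF2, a transcription factor gene, rose by 0.53 ± 0.12 (adjusted p = 0.0197). That call was lost without DMSO replicate 1 (adjusted p = 0.0671), DMSO replicate 3 (0.0563), simvastatin replicate 2 (0.0669) or simvastatin replicate 3 (0.0542), and with only the groups compared in the fit (0.0638). RHOB rose by 0.85 ± 0.04.

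Genes of mitosis fell without exception. All 29 measured members fell (29 adjusted over the list alone), with a mean log2 change of -0.63 (camera, adjusted p = 2.12e-34). HMMR, which encodes a spindle protein, was 2.75-fold lower (-1.46 ± 0.06, adjusted p = 9.64e-06). KIF20A (-1.14 ± 0.05) and KIF18A (-0.89 ± 0.06) encode mitotic kinesins, and BUB1 (1.99-fold lower) a kinase of the spindle checkpoint. Genes of DNA replication moved less and in both directions. Among 25 measured members 8 fell and 3 rose (13 and 4 adjusted over the list alone). MCM3 (-0.36 ± 0.04) and MCM2 (-0.33 ± 0.04), subunits of the replicative helicase, were among those that fell, while CCNE1, which encodes cyclin E1 and acts at entry into S phase, rose by 0.61 ± 0.06. Only 1 member rose without DMSO replicate 2 or 3 or simvastatin replicate 1. This list shifted downward (mean -0.08, adjusted p = 0.00729), with an adjusted p = 0.325 with an estimated correlation. Among the CDK inhibitor and cyclin genes 1 of 9 fell, RBL1 (1 adjusted over the list alone; adjusted p for the list = 0.533), a call lost without DMSO replicate 1 (adjusted p = 0.0769) or 3 (0.0803) or simvastatin replicate 1 (0.0712) or 3 (0.0745).

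Genes of noradrenergic identity, the transcription factors and catecholamine enzymes typical of sympathetic neuroblasts, fell in 11 of 18 cases and rose in 1 (12 and 1 adjusted over the list alone). Without simvastatin replicate 3, 10 fell and 2 rose. DBH, which makes noradrenaline, went from 9.27 ± 0.02 (SD, n = 3) to 8.06 ± 0.05, 2.32-fold lower (adjusted p = 4.77e-06). ALK, a receptor tyrosine kinase gene, fell by 0.82 ± 0.05 (SE) on the log2 scale, the transcription factor gene ISL1 by 0.74 ± 0.04 and CHGA, which encodes the granule protein chromogranin A, by 0.70 ± 0.05. The list had an adjusted p of 1.16e-06, and an adjusted p = 0.0859 with an estimated correlation. Neuronal genes went both ways, with 2 of 13 rising and 6 falling (3 and 7 adjusted over the list alone; adjusted p for the list = 0.271). VGF, a secreted neuropeptide precursor, rose by 1.09 ± 0.06, and DCX, a microtubule protein of young neurons, fell by 0.67 ± 0.04. Among 18 mesenchymal markers 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.988), with the matrix proteoglycan genes LUM (-1.14 ± 0.07) and DCN (-0.98 ± 0.06) lower. The mean of this list was -0.06 and its median 0.05, and 1 member rose, in place of 3, without DMSO replicate 2, simvastatin replicate 1 or 3 or simvastatin plus mevalonate replicate 1. Of 9 Schwann and glial markers 0 changed (limma; 0 at an unadjusted p under 0.05; adjusted p for the list = 0.629), and of 6 blood and endothelial markers 0 changed (1 at an unadjusted p under 0.05; adjusted p = 0.927), with 1 called higher without DMSO replicate 1.

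The remaining lists did not shift against the other genes. In the p53 target list 4 of 15 members rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.927), with SESN2, which is also on the ATF4 list, up and TP53I3 at -0.91 ± 0.07, and 2 members rose, in place of 4, without DMSO replicate 2 or 3 or simvastatin replicate 2. Among 14 BCL2 family genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.615), with the pro-apoptotic PMAIP1 at 0.74 ± 0.06 and the likewise pro-apoptotic BMF at -0.53 ± 0.04. The other fall, that of BID, was called with all arrays and without simvastatin replicate 1 and lost without any other single array, with adjusted p up to 0.128. In this family 2 members rose, in place of 1, without DMSO replicate 2 or simvastatin replicate 1. In the hypoxia and glycolysis list 4 of 15 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.615), with VEGFA, an angiogenic growth factor gene, at 0.66 ± 0.09 and ADM at -0.64 ± 0.08. Heat shock genes rose in 3 of 8 cases and fell in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.615). Of 8 NRF2 targets 2 rose (2 rose and 2 fell adjusted over the list alone; adjusted p = 0.615), with TKT at 0.35 ± 0.04 and TXNRD1 at 0.31 ± 0.05, and 1 also fell without simvastatin replicate 1. Of 18 autophagy and lysosome genes 2 rose (2 adjusted over the list alone; adjusted p = 0.406), SQSTM1 and TFEB. Both calls were lost without DMSO replicate 2 (adjusted p = 0.0833 and 0.0912) or simvastatin replicate 3 (0.0711 and 0.0744), and 1 of them without DMSO replicate 1 or 3 or simvastatin replicate 1 or 2. Of 5 LXR targets 1 fell, LPCAT3 at -0.42 ± 0.04 (1 adjusted over the list alone; adjusted p = 0.621). Of 6 genes of ubiquinone and dolichol synthesis 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.988), COQ8A and COQ9. Both calls were lost without DMSO replicate 2 (adjusted p = 0.0578 and 0.0835), DMSO replicate 3 (0.0955 and 0.0782) or simvastatin replicate 1 (0.0939 and 0.059), COQ8A also without DMSO replicate 1 or simvastatin replicate 3 and COQ9 without simvastatin replicate 2. In 3 lists 0 members changed in the limma fit, also when adjusted over the list alone. These were the 12 measured YAP/TEAD targets (0 at an unadjusted p under 0.05; adjusted p = 0.864), the 3 measured genes of protein prenylation (0 at an unadjusted p under 0.05; adjusted p = 0.318) and the 15 interferon response genes (1 at an unadjusted p under 0.05; adjusted p = 0.615), of which 1 was called lower without DMSO replicate 2. The mean, the median and the camera direction differed in sign for the LXR, ubiquinone and dolichol, YAP/TEAD and mesenchymal lists.

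Several of the largest changes lay outside the lists. MAP2K6, a kinase upstream of p38, fell from 7.50 ± 0.10 (SD, n = 3) to 5.55 ± 0.14, 3.85-fold lower (adjusted p = 1.72e-05). RGS13, a regulator of G-protein signalling, was 3.65-fold lower and STC1, a secreted glycoprotein, 3.08-fold lower. TM4SF4 (-1.58 ± 0.07), FGL1 (-1.57 ± 0.08), RPH3A (-1.32 ± 0.14) and LINGO4 (-1.29 ± 0.10) also fell. ULBP1, a ligand of the natural killer cell receptor NKG2D, rose by 1.62 ± 0.24 (adjusted p = 0.00242), PTCHD1 by 1.54 ± 0.13 and LONRF2 by 1.24 ± 0.05. With simvastatin, RGS13 (4.31 to 4.45) and FGL1 (4.60 to 4.84) lay below 5.18, the median of all probesets. ULBP1 did so with DMSO (4.15 to 4.97), so the sizes of these changes are poorly determined. In all 12 of 29 lists shifted, 9 upward and 3 downward. With an estimated correlation 5 did so, with far larger adjusted p than at the preset correlation. By camera these were mitosis (0.00213), ATF4 targets (0.00232), cholesterol synthesis (0.00497), SRF/MRTF targets (0.00786) and fatty acid synthesis (0.0327). By fry 19 of 29 lists moved 1 way.

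Next, simvastatin plus mevalonate was compared with simvastatin alone, to determine which of these changes depended on mevalonate. The picture was the reverse of the first comparison. Mitosis genes rose, and genes of cholesterol and fatty acid synthesis and of the ATF4 and SRF/MRTF lists fell. In total 1642 genes changed (limma, adjusted p under 0.05), 791 upward and 851 downward, with 44 at least 2-fold. RGS13 rose 3.21-fold with mevalonate (log2 change 1.68 ± 0.08, adjusted p = 1.43e-05), and MAP2K6 (1.48 ± 0.10), FGL1 (1.45 ± 0.08), TM4SF4 (1.38 ± 0.07), PRR16 (1.31 ± 0.06), LINGO4 (1.28 ± 0.10), RPH3A (1.17 ± 0.14), DBH (1.15 ± 0.04), LIX1 (1.14 ± 0.05) and STC1 (1.08 ± 0.06) followed. Leaving microRNAs aside, the largest falls were those of HS3ST3A1, a heparan sulfate sulfotransferase gene (-1.66 ± 0.08), PTCHD1 (-1.65 ± 0.13) and DHCR7 (-1.61 ± 0.08). CREB5 (-1.40 ± 0.10), ACSS2 (-1.34 ± 0.11), HGF (-1.27 ± 0.06), JUND (-1.13 ± 0.05), ULBP1 (-1.12 ± 0.24), TCEAL7 (-1.11 ± 0.10) and TRIB3 (-1.11 ± 0.12) fell as well. HMGCS1 fell by 1.06 ± 0.05, RHOB by 1.02 ± 0.04 and KLF2 by 0.70 ± 0.12 on the log2 scale. The values of DHCR7 were identical on the 3 arrays with mevalonate, and its error comes from the spread shared by all arrays. Identical values also occurred in other genes. STC1 stood at 7.42 on simvastatin plus mevalonate replicates 1 and 2. ACSS2 stood at 6.25 on DMSO replicate 3 and on simvastatin plus mevalonate replicate 1. The ULBP1 call was lost without simvastatin replicate 2, simvastatin replicate 3, simvastatin plus mevalonate replicate 1 or simvastatin plus mevalonate replicate 3, with adjusted p up to 0.0668.

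By list, 10 of 29 shifted with mevalonate, 2 upward and 8 downward. Of 29 mitosis genes 25 rose and 0 fell (28 rose adjusted over the list alone; mean 0.49, adjusted p = 2.02e-29), with HMMR at 1.07 ± 0.06 and KIF20A at 0.92 ± 0.05. Of 18 noradrenergic genes 9 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.000111, and adjusted p = 0.170 with an estimated correlation), with 2 falling without simvastatin replicate 3. Cholesterol synthesis genes fell in 9 of 14 cases (10 fell and 1 rose adjusted over the list alone; mean -0.42, adjusted p = 1.88e-08) and fatty acid synthesis genes in 10 of 14 (13 adjusted over the list alone; adjusted p = 1.23e-11). ATF4 targets fell in 13 of 18 cases (13 adjusted over the list alone; adjusted p = 1.78e-10), SRF/MRTF targets in 8 of 13 (9 adjusted over the list alone; adjusted p = 2.71e-08) and immediate early and KLF genes in 12 of 20 (13 adjusted over the list alone; adjusted p = 2.48e-09), among them IER3 (-1.08 ± 0.07), DUSP5 (-1.06 ± 0.07) and JUN (-0.90 ± 0.08). Endoplasmic reticulum chaperone genes fell in 4 of 11 cases (4 adjusted over the list alone; adjusted p = 0.00946, and adjusted p = 0.0822 with an estimated correlation), with XBP1 at -0.75 ± 0.06. In the sterol uptake and sensing list 3 of 7 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0304, and adjusted p = 0.232 with an estimated correlation). Its call was lost without simvastatin plus mevalonate replicate 3 (adjusted p = 0.0624), and that of the member that rose without any single array but DMSO replicate 2 and simvastatin plus mevalonate replicate 3. Genes of DNA replication rose in 4 and fell in 6 of 25 cases (5 and 6 adjusted over the list alone; adjusted p = 0.803), with CCNE1 at -0.73 ± 0.06, CCNE2 at -0.35 ± 0.04 and MCM3 at 0.25 ± 0.04.

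The other 18 lists did not shift with mevalonate. The adjusted p was 0.0551 for autophagy and lysosome, 0.102 for ribosome biogenesis, 0.111 for hypoxia and glycolysis, 0.213 for prenylation and 0.247 for serine, glycine and one-carbon genes. It was 0.450 for the BCL2 family, 0.506 for heat shock, 0.652 for blood and endothelial markers, 0.666 for NRF2 targets, 0.803 for neuronal genes, and 0.900 for p53 targets and for CDK inhibitors and cyclins. For YAP/TEAD targets, Schwann and glial markers and interferon response genes it was 0.982, for mesenchymal markers 0.987, and for LXR targets and ubiquinone and dolichol synthesis 0.993. In the YAP/TEAD list 1 of 12 members changed (DOCK5, -0.18 ± 0.05, adjusted p = 0.0492), a call lost under 12 of the alternatives, and in the Schwann and glial list 1 of 9 (L1CAM, -0.27 ± 0.06). The L1CAM call (adjusted p = 0.0245) was lost without simvastatin replicate 1 or 3 and without simvastatin plus mevalonate replicate 1 or 3, with adjusted p up to 0.0882. The mean, the median and the camera direction differed in sign for 8 lists, LXR, ubiquinone and dolichol, YAP/TEAD, DNA replication, serine and glycine, neuronal, mesenchymal and interferon. With an estimated correlation 6 lists shifted, and by fry 17 moved 1 way. The 6 lists, with camera's adjusted p, were mitosis (0.00334), ATF4 (0.00804), SRF/MRTF (0.00804), cholesterol synthesis (0.0104), immediate early and KLF (0.0203) and fatty acid synthesis (0.0230).

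The comparisons were then set side by side for the 1988 genes that simvastatin changed. Mevalonate moved 1291 of them back (64.9%), that is, they also changed between simvastatin alone and simvastatin plus mevalonate in the opposite direction. These were 618 of the 890 genes that had risen and 673 of the 1098 that had fallen, and 0 genes changed further in the same direction. Independent sets of calls of these sizes would share 50.9 genes that rose and then fell and 58.4 that fell and then rose. On average the means moved most of the way to DMSO. The median share of the change that was undone was 0.80, with quartiles of 0.62 and 1.01. Of the called genes 85.6% moved at least 0.5 of the way, and of the genes changed at least 2-fold 97.6% were moved back. HMGCS1 and ASNS lay 36.3% and 47.4% of their rise above DMSO, and STC1 33.6% of its fall below.

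Since the simvastatin arrays enter both comparisons, some opposition arises without any effect. Over all 14884 genes, 75.9% moved in opposite directions, against 66.7% in simulated arrays with no differences. The log2 changes of the comparisons correlated across genes with r = -0.81, against -0.50 in these simulations, and genes are not independent replicates. The covariance was -0.0332, against -0.00566 simulated. With measured simvastatin effects and no effect of mevalonate, the simulations moved back 0% of the called genes, and with a full return 90.7%. The first value was nearly fixed in advance, since no gene differed by construction between the simulated groups with and without mevalonate. The second used the estimated changes of genes already called, which selection can enlarge, so it may be too high. With 3 arrays per group the simvastatin arrays could not be split between the comparisons with at least 2 in each part, so part of the overlap of calls beyond that of independent sets can come from the shared arrays.

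**Figure D2:**
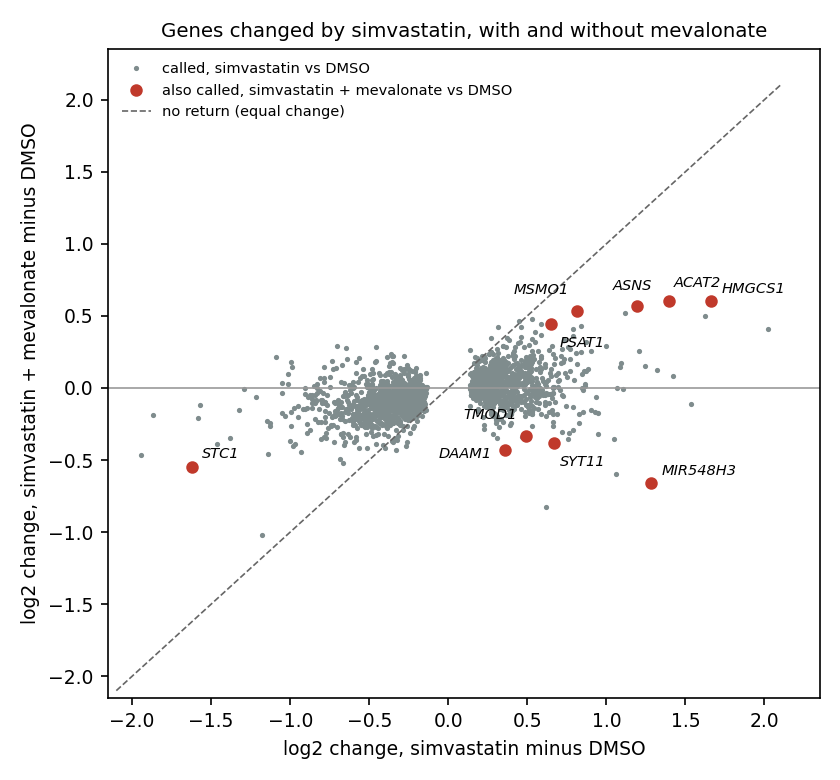
Log2 change with simvastatin against DMSO (horizontal axis) and with simvastatin plus mevalonate against DMSO (vertical axis) for the 1988 genes that simvastatin changed, 1 point per gene; the DMSO arrays enter both axes. Genes on the dashed line would have kept their full change, most points lie near 0 on the vertical axis, and the 10 genes in red also differed from DMSO with mevalonate, from STC1 at -0.55 and MIR548H3 at -0.66 to HMGCS1 at 0.60.

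Finally, simvastatin plus mevalonate was compared with DMSO, to see what was left of the drug's effect. The remaining differences were small. Genes of cholesterol synthesis and ATF4 targets stayed higher, and MEG3, an imprinted long non-coding RNA, was lower. Only 11 genes differed (limma, adjusted p under 0.05), 5 higher and 6 lower, with 0 at 2-fold, while 1635 had an unadjusted p under 0.05. Groups did not overlap for 16.5% of all genes, where chance gives 10% for a single gene. Genes vary together, and this share was not computed for other groupings of the arrays. It therefore cannot show whether more genes differed than were called. HMGCS1 was 1.52-fold higher than with DMSO (log2 difference 0.60 ± 0.05, adjusted p = 0.0129), as were ACAT2 (0.60 ± 0.05), ASNS (0.57 ± 0.06), MSMO1 (0.53 ± 0.05), another enzyme of cholesterol synthesis, and PSAT1 (0.44 ± 0.04), an enzyme of serine synthesis. MEG3 was 1.63-fold lower (-0.71 ± 0.08, adjusted p = 0.0222) and had not changed with simvastatin alone (-0.22, adjusted p = 0.115). STC1 was lower (-0.55 ± 0.06), and so were DAAM1 (-0.43 ± 0.05), a formin that nucleates actin, SYT11 (-0.38 ± 0.04) and TMOD1 (-0.33 ± 0.04), which caps actin filaments. The last 3 had risen with simvastatin alone and went below DMSO with mevalonate, and MIR548H3, named here after its values were seen, did the same (-0.66 ± 0.08). RHOB (-0.17 ± 0.04, adjusted p = 0.209) and KLF2 (-0.17 ± 0.12, adjusted p = 0.653) did not differ.

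This count depended strongly on the arrays and settings. It was 0 without any 1 of the 3 DMSO arrays and 0 without simvastatin plus mevalonate replicate 1, 2 without replicate 2 and 3 without replicate 3 of that group. It was 223 with a trended and robust eBayes (70 higher, 153 lower), 99 with an offset of 16 (24 higher, 75 lower) and 98 among genes that were not dim (25 higher, 73 lower). HMGCS1, the gene with the lowest adjusted p, had 0.0713, 0.0795 and 0.056 without DMSO replicates 1, 2 and 3 and 0.051 without simvastatin plus mevalonate replicate 1, and MEG3 had 0.111 to 0.128 without a DMSO array.

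In this comparison 9 of 29 lists shifted, 4 upward and 5 downward. Cholesterol synthesis genes were higher (3 of 14 changed, 5 adjusted over the list alone; mean 0.25, adjusted p = 5.46e-10), as were ATF4 targets (2 of 18 changed, 10 adjusted over the list alone; mean 0.22, adjusted p = 4.85e-13). The calls of these single genes, unlike the shifts of the lists, were lost without any 1 DMSO array or simvastatin plus mevalonate replicate 1. Those of the ATF4 targets were also lost without replicate 2 or 3 of that group. Without its replicate 3 only 1 of the 3 cholesterol synthesis calls was left. Mitosis genes were lower by a mean of -0.14, with 27 of 29 members lower, 0 changed and 16 adjusted over the list alone (adjusted p = 5.35e-15). DNA replication genes were lower in 25 of 25 cases (mean -0.12, 0 changed, 4 adjusted over the list alone, adjusted p = 1.48e-11). Against DMSO their mean was -0.08 with simvastatin alone, so they did not move nearer to DMSO with mevalonate. The shifts of these 4 lists held in camera with an estimated correlation, but for DNA replication only just (adjusted p = 0.0488). For each of the others the adjusted p was 0.00846. The other 5 did not. Serine, glycine and one-carbon genes were higher (adjusted p = 0.00242, and adjusted p = 0.0680 with an estimated correlation), and so were NRF2 targets (0.0128, and adjusted p = 0.113 with an estimated correlation). Noradrenergic genes (0.00219, and adjusted p = 0.240 with an estimated correlation) and immediate early and KLF genes (0.00118, and adjusted p = 0.138 with an estimated correlation) were lower. The immediate early and KLF list had a mean of -0.10 here, while simvastatin alone had raised it to 0.29 against DMSO. Neuronal genes were lower too (0.0465, and adjusted p = 0.155 with an estimated correlation), a call that was also lost without DMSO replicate 1 (0.103), DMSO replicate 2 (0.0957), simvastatin plus mevalonate replicate 2 (0.0938) or 3 (0.101) and with dim genes left out (0.114).

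The remaining lists did not shift against the other genes in this comparison, though 4 of 14 fatty acid synthesis genes were higher when adjusted over the list alone. The adjusted p was 0.0844 for sterol uptake and sensing and for fatty acid synthesis, 0.0916 for ribosome biogenesis, 0.215 for hypoxia and glycolysis and 0.257 for blood and endothelial markers. It was 0.362 for LXR targets, 0.366 for autophagy and lysosome, 0.437 for endoplasmic reticulum chaperones, and 0.454 for mesenchymal and for Schwann and glial markers. For interferon response genes it was 0.506, for heat shock and for CDK inhibitors and cyclins 0.522, for the BCL2 family 0.591, for prenylation 0.758 and for p53 targets 0.819. It was 0.887 for YAP/TEAD targets and 0.950 for SRF/MRTF targets and for ubiquinone and dolichol synthesis. The mean, the median and the camera direction differed in sign for the prenylation, p53 and mesenchymal lists, and by fry 10 lists moved 1 way.

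**Figure D3:**
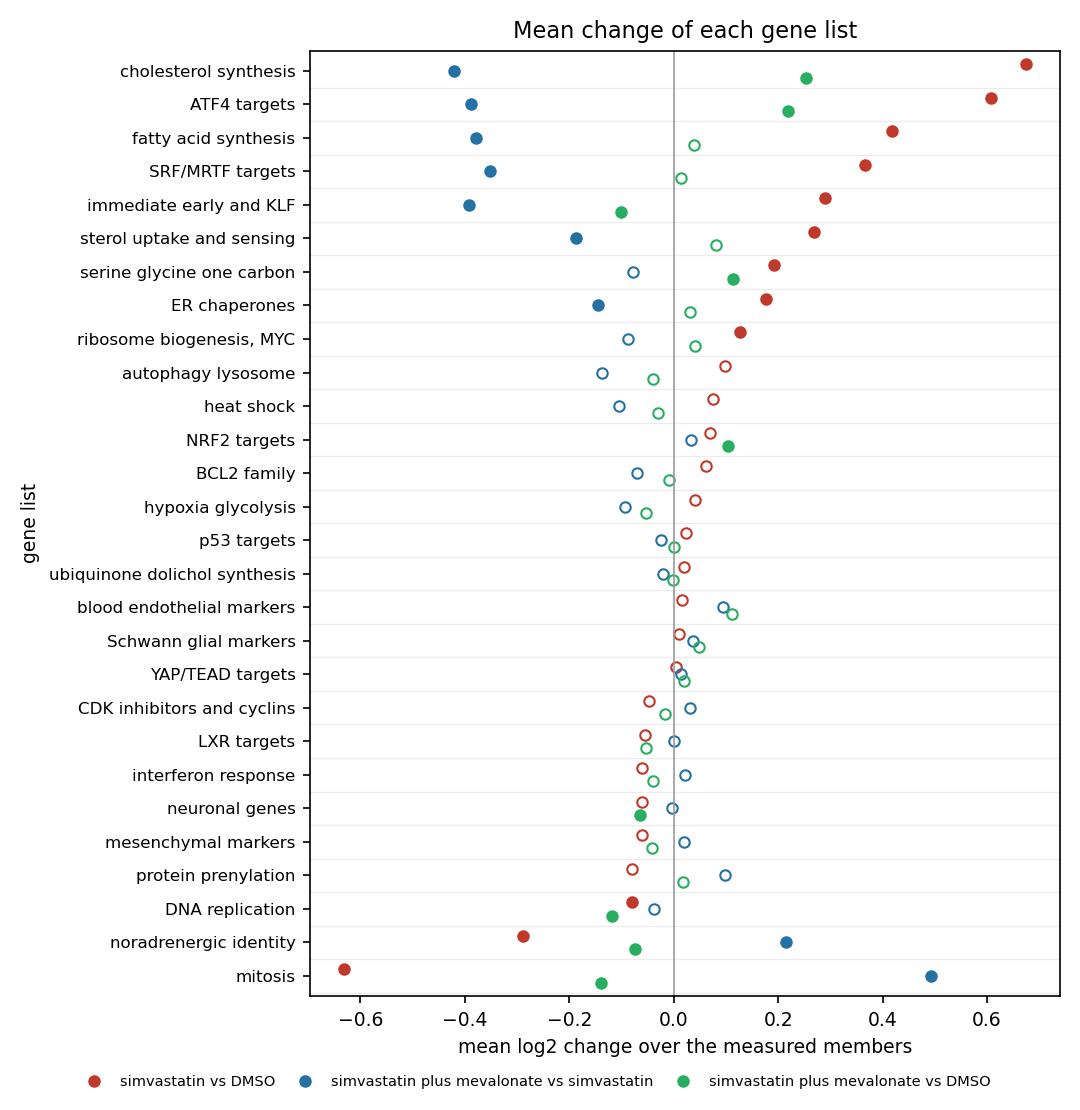
Mean log2 change over the measured members (horizontal axis) of each of 28 gene lists (vertical axis) in the 3 comparisons. Each point is 1 list in 1 comparison, filled where camera's adjusted p was under 0.05 and open otherwise; the cholesterol synthesis list stood at 0.67 with simvastatin and 0.25 with simvastatin plus mevalonate, both against DMSO.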

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

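The tests of probesets near background and of an own effect of mevalonate were chosen only after the result was seen, and so was the region between DLK1 and DIO3 itself.

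Among the 37519 probesets without a gene name, which the comparisons of named genes leave out, 1250 differed between simvastatin and DMSO (limma, adjusted over all probesets), 521 higher and 729 lower. This is 3.33% of them, against 7.59% of the named probesets, and their median level was 4.85 against 5.98. Between simvastatin alone and simvastatin plus mevalonate 960 differed, and between simvastatin plus mevalonate and DMSO 6.

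Genes of the imprinted interval between DLK1 and DIO3, a cluster of microRNA and long non-coding RNA genes, were lower together when mevalonate was added to simvastatin. With simvastatin alone they had a median log2 difference from DMSO of 0.19, with 45 of 57 higher, so part of the fall may be a return. This was not tested, and the same simvastatin arrays enter both differences. MEG3 (-0.22) and DLK1 (-0.07) were not higher with simvastatin alone than with DMSO. Neighbourhood was taken from the RefSeq table (GCF_000001405.40, GRCh38.p14), 57 of its 122 genes there were measured, 53 of them microRNA genes, and their median log2 difference between simvastatin plus mevalonate and simvastatin alone was -0.37, with 51 of 57 lower, 25 called lower and 0 called higher (limma), among them MEG3 (-0.49), DLK1 (-0.32), MIR493 (-1.44) and MIR329-1 (-1.01). The tables argue against 1 deviating array, since the median was still -0.373 in the least favourable case of leaving out 1 of the 6 arrays, and against a shift of all microRNA probesets, since the 1019 microRNA genes outside the interval had a median of -5.07e-05 and random sets of them ran from -0.138 to 0.124. Dimness stays open, since the 27 members above the median level of all probesets had a median of -0.316 (bootstrap interval -0.438 to -0.165), which reaches past 0.5 of the full size (-0.187). The bootstrap resampled the 27 members as if independent and leaves out the spread between arrays. An own effect of mevalonate, which may lower the genes between DLK1 and DIO3 below DMSO (median -0.265, 48 of 57 lower), stays open too, because no group received mevalonate alone.

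With mevalonate the cholesterol synthesis genes and the ATF4 targets stayed above DMSO. The called rising members of the cholesterol list kept 31.1% of their rise, and those of the ATF4 list 36.3%. Random sets of other rising genes matched on the size of the rise kept a median of 5.34% (-13.7 to 23.3) and 4.61% (-11.3 to 19.4). The match was loose for the largest rises, which weigh most in the percent. Only 18 genes rose at least 2-fold, list members among them, so these were matched in part to smaller rises. The values argue against an equally incomplete return of all genes that rose only as far as this match holds. A deviating DMSO array is argued against as well, since the mean differences from DMSO were at least 0.243 and 0.211 with any DMSO array left out. A remaining shortage of mevalonate products may account for this as a hypothesis, which was not tested because 1 dose of mevalonate was used.

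The 29 mitosis genes, all lower with simvastatin, are bright (mean level 9.19), so a shift of all bright genes was weighed. Random sets of genes matched on mean level had a median mean change of -0.0150, the lowest being -0.188, against -0.63 for the list, which argues against it. A lower share of dividing cells and lower transcription within dividing cells may both give this pattern, and arrays of pooled cells cannot separate them, so both stay untested.

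Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and in each case the real split was the only 1 of 10 with a result as large. For simvastatin against DMSO the real count was 1988 and the highest other 0, for changes of at least 2-fold 41 and 0, for simvastatin plus mevalonate against simvastatin 1642 and 0, and against DMSO 11 and 1. For the lists shifted the real counts were 12, 10 and 9 in the same order, and the highest others 6, 6 and 4. For the genes moved back by mevalonate, 1 of 100 drawn assignments of the 9 arrays to 3 groups, the real one, reached 1291, the highest other being 1117. Of the draws 96 called 0 genes (limma) in the first comparison, so that none could be moved back, and the draw with 1117 keeps the 3 simvastatin arrays together and mixes the other arrays. The draws therefore do not test the effect of mevalonate.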

How the results depend on the processing

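The count over all probesets and the fit of protein-coding genes were chosen only after the data were seen. The number of genes that differed between simvastatin plus mevalonate and DMSO, 11, was the least stable result. It was 223 with a trended and robust eBayes, 99 with an offset of 16, 98 with dim genes left out, 51 with array quality weights, 49 among protein-coding genes, and 0 with only the groups compared in the fit or at an adjusted p under 0.01. Leaving out 1 array gave 0 to 12. Over all probesets, 7 probesets differed, 6 of them without a gene name. The cause was not tested, apart from the smaller number of genes or arrays in some settings. At an adjusted p under 0.01, 1034 genes differed between simvastatin and DMSO and 832 between simvastatin plus mevalonate and simvastatin. Genes changed at least 2-fold numbered 23 with the offset, which shrinks changes of dim genes, and over all probesets 120 probesets did so. The percent moved back was 85.6 by the rule of at least 0.5 of the way, 97.6 among genes changed 2-fold, and 54.2 to 72.1 with 1 array left out. Lists shifted numbered 5, 6 and 4 with an estimated correlation, in the order of the report, and 19 and 17 by fry in the first comparisons. With 1 array left out, counts ran from 1461 to 1744 and from 1121 to 1482 genes, from 40 to 46 at 2-fold, and 12, 8 to 11 and 8 to 12 lists.

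The replicate numbers do not pair the arrays. Deviations of arrays with the same number correlated from -0.081 to 0.050, those with other numbers from -0.040 to 0.067, and 0 arrays correlated best with their own number in both other groups. With the replicate block the counts were 1576, 1230 and 0 genes. Over all alternatives, the block included, the named genes gave 7002 results on the same side of the threshold, 253 that lost and 151 that gained a call, and the shifted lists 619 and 32 that lost it. Of the results called with the main settings or with the alternative, 0 changed direction. Results called with neither were not checked for direction. Arrays give no depth, and values near background limit dim genes: 10445 genes had a highest group mean above 5.18, the median of all probesets.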

Other observations

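All gene families in this part were chosen only after the data were seen.

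Aminoacyl-tRNA synthetases attach amino acids to transfer RNA. Of 16 measured synthetase genes with symbols ending in ARS1, 12 rose with simvastatin, 0 fell and 4 were not called (limma), with no test of enrichment, 7 of them were moved back by mevalonate, and 4 are also on the ATF4 list. CARS1 (0.84), AARS1 (0.77) and SARS1 (0.72) are examples, and the family's median log2 difference from DMSO was 0.32 with simvastatin and 0.16 with simvastatin plus mevalonate. Quantile normalization gave 13 that rose, and median centring 12.

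Kinesin genes, which encode motors that move along microtubules, went both ways. Of 39 measured, 13 fell, among them the mitotic KIF14 (1.99-fold lower) and KIF4A (1.61-fold lower), and 7 rose, among them the neuronal motors of axonal transport KIF5A (0.53), KIF5C (0.41) and KIF1A (0.40). Of the 39 genes 16 were moved back by mevalonate. With median centring 4 rose and 13 fell, with quantile normalization 7 and 12, and 0 of the called members changed sign. Of 10 ligands of natural killer cell receptors 3 rose and 0 fell, namely ULBP1 (1.62), NCR3LG1 (0.87) and PVR (0.52), and all 3 were moved back, ULBP1 with a call that was lost without some single arrays. Both other scalings gave the same counts for this family.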
